A study of Mus musculus with 15 samples.

How the data were processed

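Gene expression was measured on Illumina bead arrays in primary cultures of cortical neurons from foetal Swiss albino mice on culture day 7. Per the labels, total RNA was extracted on columns and biotinylated cRNA was prepared for hybridisation. Each of the 15 arrays held 1 sample. The labels gave 6 arrays of vehicle control, which all time points share, and 3 arrays each after 5, 15 and 24 h in 250 µM L-glutamate. No vehicle arrays were matched to the separate times. Effects of glutamate therefore cannot be told apart from those of time or harvest. The labels did not say whether arrays of one group came from separate cultures, so the p-values measure the spread between these samples, which may be in part technical.

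The deposited table held 1 value per array for 24607 probes, with no missing value, from 0.0855 to 9.87. From the values, the unit is a linear ratio: the median over the 6 control arrays was 1, within a tolerance of 1e-04, at 24606 probes, whereas the median over all 15 arrays was 1 at 65 probes. Each deposited value is therefore read as a ratio to the control median of its own probe. That division removes the absolute signal, so bright and dim probes cannot be told apart and no probe could be left out for lying near the background. The normalization before the division is not given in the sources used here. The files did not pair the probe identifiers with genes, and the gene table used here, for assembly GRCm38.p6, held none of these identifiers. No gene is named, and 30 gene lists fixed before the data were examined, cell type markers among them, were not tested.

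Log2 of the ratios as deposited was tested. The design had foreseen intensities, with a floor on low values and a filter on dim probes, and neither applies to ratios. A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), so that the 4 groups shared 1 estimate of the spread per probe. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 24607 probes. The 3 time points were each compared with the control and with each other. The median standard error of a log2 change against the control was 0.0898. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

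The rule for named items, set before the data were examined, took the probes with the largest rise and the largest fall against the control among called probes whose 3 treated arrays all lay outside the range of the 6 controls. Because no gene names could be given, it was shortened to the first probe in each direction at each time point, which gave 4 probes.

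All comparisons with the control share the same 6 arrays. Correlations and covariances of log2 changes across probes are therefore given beside the mean of 100 simulations of unchanged groups against those controls. Correlations are also given with the controls split into replicates 1 to 3 and 4 to 6. Overlaps of calls are given beside the overlap of independent lists. In the simulations the mean overlap of calls was 0 in both directions for each pair of times. Unchanged groups leave hardly any calls to overlap, so this does not show what the shared controls add where probes change. The overlap of independent lists does not include the shared controls either. The simulation did not include the deviations that same-numbered treated arrays shared.

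Whether replicate numbers pair the arrays was checked from the correlation, across probes, of each array's deviations from its group mean. Over the 9 pairs of treated arrays with the same number, r averaged 0.26 and ran from 0.14 to 0.37. All 9 pairs lay above 0.1, so the numbers were taken to pair the treated arrays. Between controls 1 to 3 and the treated arrays of the same number, r averaged -0.024 and ran from -0.15 to 0.055. The labelled number therefore did not pair the controls with them. Deviations cancel out within a treated group, so some number has to come out highest for each control, and that grouping was not tested. By mean r, controls 2 and 4 went with number 1 (0.14 and 0.14) and controls 1 and 3 with number 2 (0.18 and 0.16). Controls 5 and 6 went with number 3 (0.2 and 0.31). The planned replicate block used the labelled numbers, and no block by this grouping was fitted. The pairing comes from these correlations and not from a statement in the labels.

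The fit was tested on simulated data with known changes. At 5 h against control it recovered 32.84% of probes changed 1.25-fold, 86.57% of those changed 1.5-fold and 100% of those changed 2-fold, and 6.41% of the calls were false. The simulated noise was independent between arrays, and far fewer probes changed than were called in the real data. These rates therefore need not hold for the real data. Alternatives tried were quantile normalization, median centring, eBayes with trend and robust, array weights, a fit of the compared groups alone, a replicate block, a minimum change of 1.5-fold, controls 1 to 3 or 4 to 6 alone, and each array left out in turn. The alternatives added after the data had been seen were leaving out controls 1 and 5, covariates from the within-group deviations, the treated arrays fitted alone with and without a block, a block among them with the controls kept in the fit, 2 further fits of a test of a common factor, and a scaling of all controls to one spread.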

Results

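The study profiled the death of neurons induced by glutamate, the main excitatory transmitter, which kills cultured neurons when its receptors are overstimulated. Primary cultures of mouse cortical neurons were exposed to 250 µM glutamate for 5, 15 or 24 h (n = 3 arrays each) and compared with 6 arrays of vehicle control. Each value was a probe's ratio to its median over the controls, measured for 24607 probes. The probes are given by their identifiers because the files do not pair them with genes.

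Arrays separated by treatment time. The first principal component held 43.5% of the variance, and the mean score on it was -17.8 ± 2.25 (SD, n = 6) in the controls, -11.2 ± 0.416 (SD, n = 3) at 5 h, 26.9 ± 1.75 (SD, n = 3) at 15 h and 19.9 ± 1.44 (SD, n = 3) at 24 h. The second component held 12.7% of the variance. On it the 5 h arrays averaged 16.6 ± 2.4 (SD, n = 3), while the controls ran from -16.2 to 8.62, with replicates 1 and 5 nearest to the 5 h arrays. The spread of log2 ratios across the probes of an array was 0.146 ± 0.0299 (SD, n = 6) in the controls, 0.211 ± 0.0122 (SD, n = 3) at 5 h, 0.314 ± 0.00872 (SD, n = 3) at 15 h and 0.276 ± 0.0085 (SD, n = 3) at 24 h.

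**Figure D1:**
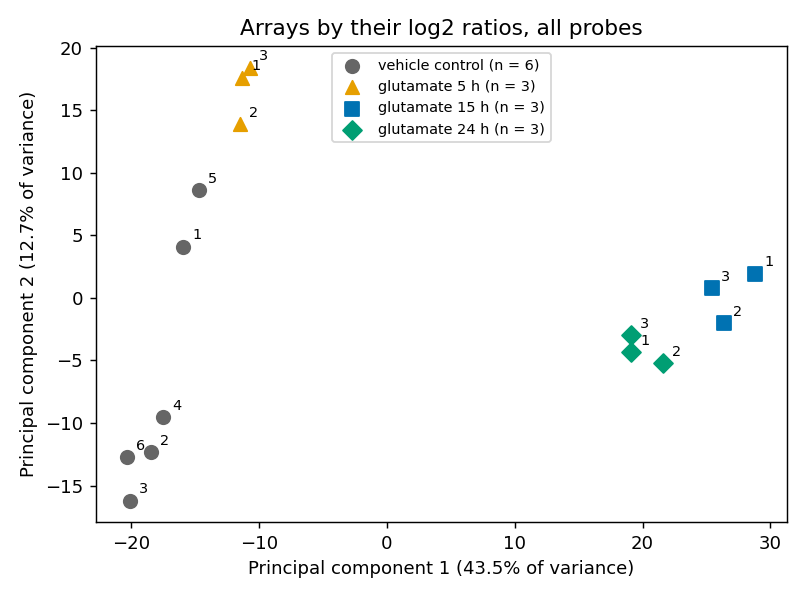
Each point is 1 array, numbered by replicate, placed by its scores on the first (x axis, 43.5% of variance) and second (y axis, 12.7%) principal components of the log2 ratios, in arbitrary units. The arrays of 15 h and 24 h lie apart from the controls and the 5 h arrays on the x axis, and controls 1 and 5 lie between the other controls and the 5 h arrays on the y axis.

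The first comparison asked which transcripts had changed after 5 h. Probe ILMN_1231590 rose most, from a ratio of 1.08 ± 0.239 (SD, n = 6) in the controls to 4.83 ± 0.431 (SD, n = 3), a log2 change of 2.18 (SE 0.127, limma adjusted p = 8.91e-10). Probe ILMN_2662482 fell most, from 1.05 ± 0.125 (SD, n = 6) to 0.385 ± 0.062 (SD, n = 3), a log2 change of -1.45 (SE 0.112, limma adjusted p = 6.06e-08). In all, 1597 probes were called, or 6.49% of those tested, of which 665 were higher and 932 lower than in the control. Most changes were small. The median absolute log2 change of the called probes was 0.403, and 216 probes changed at least 1.5-fold, 122 upwards and 94 downwards. Leaving out replicate 1 of the 5 h arrays gave 644 called probes and leaving out replicate 3 gave 786, with 419 higher and 367 lower, so the excess of lower probes turned, and leaving out replicate 2 took the higher probes to 351. Quantile normalization gave 707 called probes. It gave every array a spread of 0.218, wider than that of any control and narrower than that of any 15 h or 24 h array. That may by itself lower the counts. Without controls 1 and 5, an alternative chosen after the data had been seen, 2761 probes were called, 1494 of them shared with the 1597.

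At 15 h the response was broader. Probe ILMN_2733448 rose from 1.06 ± 0.188 (SD, n = 6) in the controls to 8.28 ± 0.483 (SD, n = 3), a log2 change of 2.98 (SE 0.119, limma adjusted p = 4.86e-13). Probe ILMN_2776687 fell from 0.863 ± 0.336 (SD, n = 6) to 0.0929 ± 0.00654 (SD, n = 3), a log2 change of -3.11 (SE 0.235, limma adjusted p = 1.76e-09), or of -1.59 with quantile normalization (limma adjusted p = 0.0179). Quantile normalization sets the lowest value of every array equal. ILMN_2776687 was the lowest on control 1 and on every 15 h array, so part of that drop follows from the step itself. Of the 4962 probes called (20.2%), 2401 were higher and 2561 lower. At least 1.5-fold changes were found at 1618 probes, 697 upwards and 921 downwards, and at least 2-fold changes at 343. Quantile normalization on top of the deposited ratios, which widened the controls and narrowed the 15 h arrays, gave 1748 called probes.

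At 24 h the same 2 probes led. ILMN_2733448 stood at 8.31 ± 1.36 (SD, n = 3), a log2 change of 2.98 (SE 0.119, limma adjusted p = 4.46e-13), and ILMN_2776687 at 0.101 ± 0.00265 (SD, n = 3), a log2 change of -2.98 (SE 0.235, limma adjusted p = 7.45e-09), or of -1.59 with quantile normalization (limma adjusted p = 0.0185). ILMN_2776687 was also the lowest on every 24 h array, so quantile normalization gives it the same value as at 15 h. Of the 3923 probes called (15.9%), 1850 were higher and 2073 lower. At least 1.5-fold changes were found at 1102 probes and at least 2-fold changes at 167. Quantile normalization gave 1642 called probes.

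**Figure D2:**
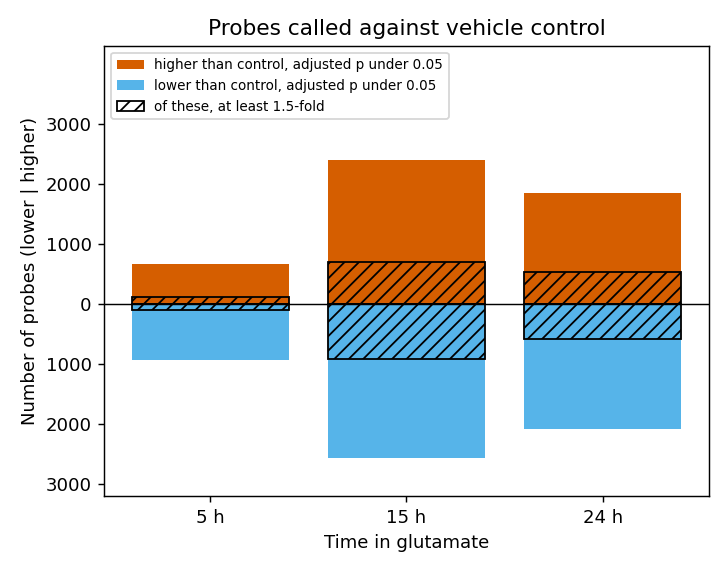
Bars give the number of probes called against vehicle control at each time in glutamate (x axis), with higher probes above 0 and lower probes below 0 on the y axis. Hatched parts are the probes that also changed at least 1.5-fold, and the total is highest at 15 h, with 4962 probes.

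The second question was how the profiles moved with time in glutamate. Without vehicle arrays at each time, a difference between times may in part reflect time or harvest rather than glutamate. Between 5 h and 15 h, 3610 probes differed, 1899 of them higher at 15 h and 1711 lower. With the 9 treated arrays fitted alone, as pairs by number, 2777 were higher and 2628 lower. Between 5 h and 24 h, 2834 probes differed, 1543 higher and 1291 lower at 24 h, and 4712 did with the 9 treated arrays fitted alone as pairs. The 15 h and 24 h arrays differed at 15 probes, 4 higher and 11 lower at 24 h, against 1568 at an unadjusted p under 0.05. Pairs by number with the controls kept in the estimate of the spread gave 16, the 9 treated arrays fitted alone without pairs gave 88, and both together gave 209, 133 higher and 76 lower. Quantile normalization gave 1063 probes for 15 h against 5 h, 1112 for 24 h against 5 h and 0 for 24 h against 15 h. The last count lay between 0 and 4 when any 1 of the 6 arrays was left out of the fit to all groups. At 14 of the 15 probes and at 185 of the 209, the 24 h level was nearer to the control than the 15 h level.

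Early probes split by their later course. The 5 h arrays that chose these probes also enter their test against 15 h, which favours a return towards the control over a further change. Of the 665 probes higher at 5 h, 256 were lower at 15 h than at 5 h, 52 rose further and 357 were not shown to differ between these times. ILMN_1231590 belonged to those that came down, with a ratio of 1.43 ± 0.0973 (SD, n = 3) at 15 h and 1.27 ± 0.0841 (SD, n = 3) at 24 h, where it did not pass the test (log2 change 0.259, limma adjusted p = 0.207). Without controls 1 and 5, at 1.5 and 1.23, it passed at 24 h too, with a log2 change of 0.433 (limma adjusted p = 0.000928). Of the 932 probes lower at 5 h, 221 were higher at 15 h than at 5 h, 211 fell further and 500 were not shown to differ. ILMN_2662482 crossed the control level. It stood at 1.77 ± 0.269 (SD, n = 3) at 15 h, above the control (log2 change 0.754, limma adjusted p = 1.97e-05), and at 1.07 ± 0.041 (SD, n = 3) at 24 h (limma adjusted p = 0.902). Lower than the control at 15 h or 24 h were 63 of the probes that had been higher at 5 h, and 103 of those lower at 5 h were later higher. These small groups depended on single arrays and on scaling: without 5 h replicate 2 the first numbered 27, without 5 h replicate 1 the second numbered 30, and quantile normalization gave 16 and 33.

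**Figure D3:**
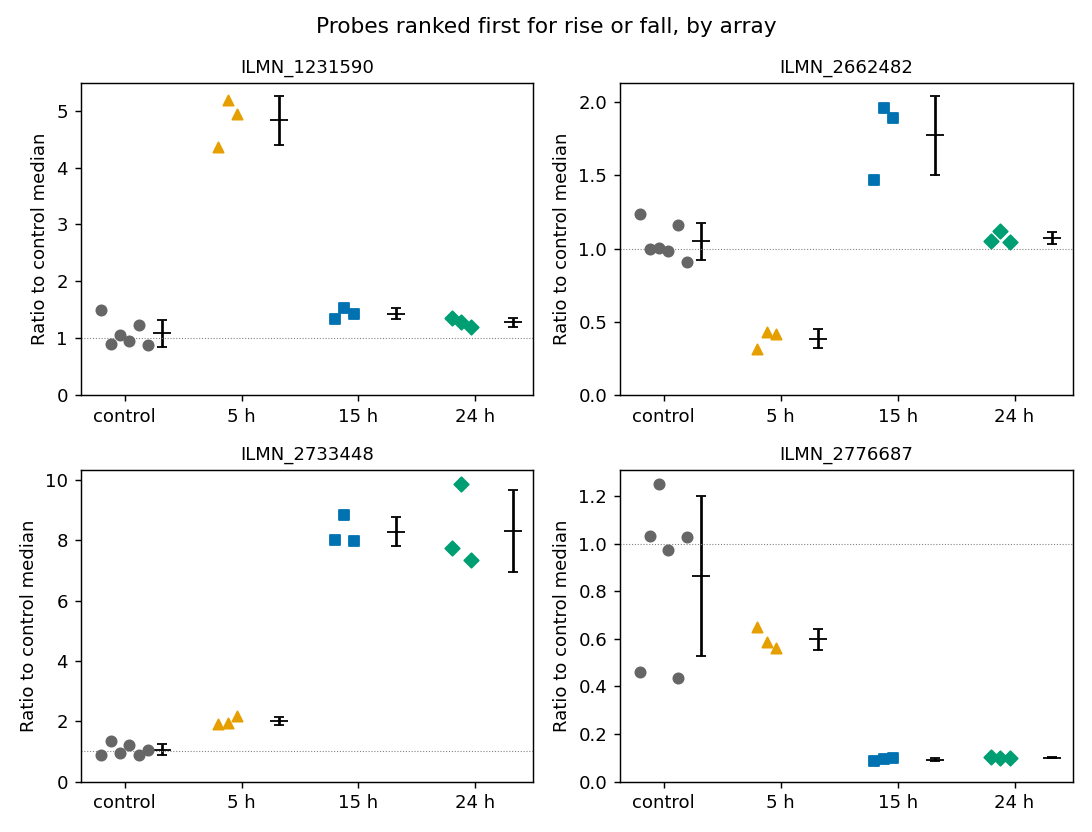
Each panel shows 1 probe's ratio to the control median (y axis, linear) on every array, by group (x axis), with black marks for the mean and SD of the group. ILMN_1231590 peaked at 5 h at 4.83, ILMN_2662482 fell to 0.385 at 5 h and reached 1.77 at 15 h, and the other probes kept their change from 15 h to 24 h.

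Among called probes, the late changes made up the largest groups. Called at 15 h and 24 h but not at 5 h were 1334 higher and 1271 lower probes. The arrays that chose these probes also enter the tests against 5 h, which favours a difference in that direction. The difference between 15 h and 5 h itself was called in that direction at 1055 and 830 of them. Both 15 h and 24 h were called as different from 5 h in that direction at 882 and 623. At 5 h ILMN_2776687 stood at 0.599 ± 0.044 (SD, n = 3), which did not pass the test (limma adjusted p = 0.374). That result rested on controls 1 and 5, at 0.461 and 0.434, while the other controls were at 0.973 or above. Without these 2 arrays the log2 change at 5 h was -0.833 (SE 0.0911, limma adjusted p = 1.43e-06). Higher at all 3 times were 159 probes and lower at all 3 were 482. Without controls 1 and 5 these numbers were 519 and 780, and with 1 array left out they ran from 78 (without 5 h replicate 2) to 274 (without control 1) and from 205 (without 5 h replicate 1) to 641 (without control 5). Quantile normalization gave 607 and 500 for the late groups, and 52 and 172 for those called at all 3 times.

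The changes at 15 h and 24 h were alike across probes, and those at 5 h were less so. Probes are not independent replicates. Across all probes the log2 changes at 15 h and 24 h correlated at r = 0.907, against 0.333 in simulated unchanged groups, and the covariance was 0.0666 against a simulated 0.00306. Both times called 1570 probes higher and 1798 lower, where independent lists would share 180.5 and 215.7, and no probe was called in opposite directions. With separate controls for each time r was 0.807 and 0.827. Between 5 h and 15 h r was 0.386, against 0.333 in simulated unchanged groups, and the covariance 0.0193 against a simulated 0.00305. They shared 252 higher and 568 lower probes, where independent lists would share 64.9 and 97, and 152 probes were called in opposite directions, 57 higher and then lower and 95 lower and then higher, where independent lists would give 69.2 and 90.9. With separate controls for each time r was 0.283 and 0.296. Between 5 h and 24 h r was 0.347, and the covariance 0.0149 against a simulated 0.00306. The simulated r of 0.333 is that of groups with no change at all. It does not measure how much of r the shared controls give where probes do change. Nor do the overlaps of independent lists include what the shared controls add to the calls in common. The 5 h and 24 h calls shared 171 higher and 503 lower probes, where independent lists would share 50 and 78.5. In opposite directions 136 were called, 51 higher and then lower and 85 lower and then higher, where independent lists would give 56 and 70.1. With separate controls for each time r was 0.223 and 0.258.

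**Figure D4:**
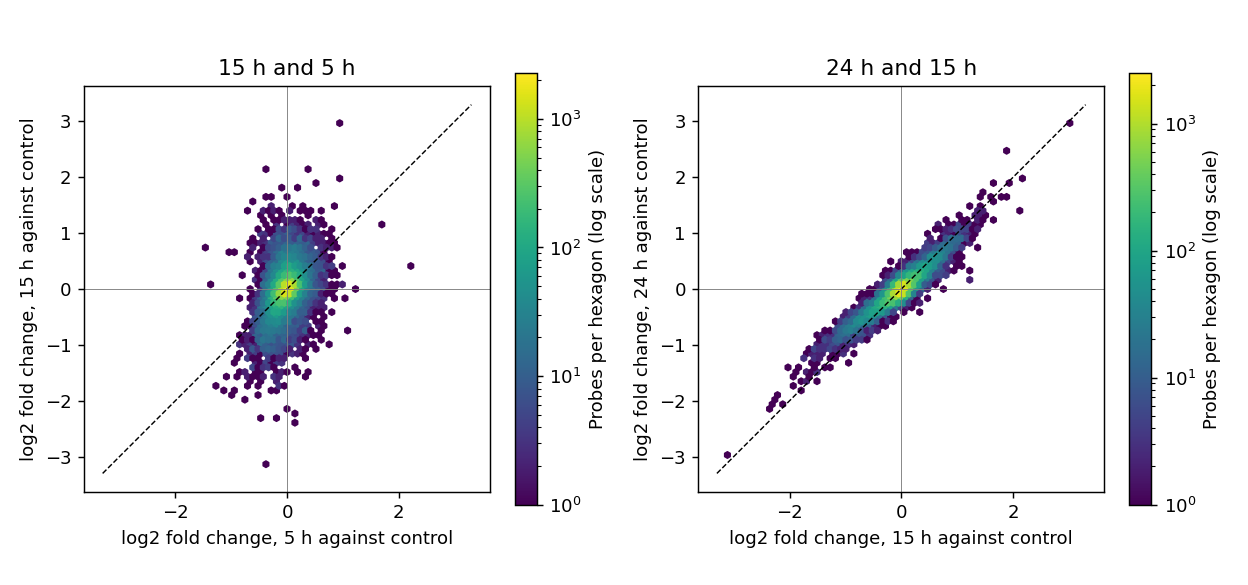
Hexagons give the number of probes (colour, log scale) by their log2 change against the control at 5 h (x) and 15 h (y) on the left, and at 15 h (x) and 24 h (y) on the right, with a dashed line of equal change. The right cloud follows the line (r = 0.907) and the left one does so less (r = 0.386).

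Changes were smaller at 24 h than at 15 h. Over the 5661 probes called on the mean of both times, the mean log2 change in the direction of the call was 0.495 at 15 h and 0.418 at 24 h, or 84.5% of it, and 71.8% of these probes changed less at 24 h. Each array was also scored over all probes along a direction of change. The direction was the mean change from the control in the 15 h and 24 h arrays of the other replicate numbers. The score was 1.01 ± 0.0647 (SD, n = 3) at 15 h and 0.85 ± 0.0361 (SD, n = 3) at 24 h. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. Within the pairs of one number the score at 24 h minus that at 15 h was -0.226, -0.115 and -0.135, a mean of -0.159 ± 0.059 (SD, n = 3), and the two-sided exact sign-change permutation p was 0.25, the smallest that 3 pairs can give. With quantile normalization, which gives all arrays the same spread, the size at 24 h was 0.98 of that at 15 h.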

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

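The tests of other groupings, of an array-wide difference in spread and of a uniform compression were set before their results were seen, and the other tests of explanations here were chosen afterwards.

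Differences between times were tested directly. They were called at 3610 probes between 15 h and 5 h, at 15 between 24 h and 15 h and at 2834 between 24 h and 5 h. On the log2 scale, ILMN_1231590 differed by -1.75 at 15 h and -1.92 at 24 h from 5 h. ILMN_2662482 differed by 2.2 at 15 h and 1.49 at 24 h from 5 h, and by -0.714 between 24 h and 15 h. ILMN_2733448 differed by 2.05 at 15 h and 2.04 at 24 h from 5 h. ILMN_2776687 differed by -2.69 and -2.57. No single control array stood apart from the other 5 in 12 measures, by a test that cannot flag 2 arrays lying together, as controls 1 and 5 do.

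Other groupings of the same arrays were fitted for each count, with the compared groups alone. Against the control, the real grouping gave 1015 probes at 5 h, 4583 at 15 h and 3442 at 24 h. The highest of the other splits gave 272, 3 and 6. In each case 1 of 84 splits was as large, the smallest share this test can give. That argues against chance only if the arrays are exchangeable, which a source shared between arrays would limit. Between times the real groupings gave 4285 probes for 15 h and 5 h, 52 for 24 h and 15 h, and 3356 for 24 h and 5 h. The highest other split gave 0 in each, 1 of 10 splits being as large, and 10 splits are too few for a share under 0.05.

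Vehicle control arrays 1 and 5 share raised probes: at 102 both exceeded 1.5-fold, where chance gives 1.26 and other pairs of controls gave 0 to 2. Quantile normalization left 153 such probes, but it widened these arrays and gave another pair 37, so it decides nothing about an array-wide difference in spread. With every control scaled to the lowest spread among them, 34 probes were still shared and at most 1 by any other pair, which argues against a wider spread of these arrays as the whole of it. Arrays of 5 h carrying the wrong label are argued against, since over the 2761 probes called without them controls 1 and 5 lay at a median of 0.507 and 0.579 of the way to the 5 h arrays. Both exceeded every 5 h array at 67 of the 102 probes, which were picked for being high in both. At probes picked from one of them, the other did so at 56.1% or more, where 25% is expected of another 5 h array. That passed the bound chosen to count against a mixture with RNA of the 5 h cultures. But a single 5 h culture mixed into both arrays would carry its own high probes into both, so a mixture stays open. An inducible response that varied between control cultures may account for it and stays open too: 93.1% of the raised probes were called at some time without these arrays, against 28.5% of all probes, though handling of these cultures was not tested.

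For the smaller changes at 24 h than at 15 h, a single aberrant replicate is argued against, because the mean score difference of -0.159 was still -0.125 at its nearest to 0 with 1 replicate number left out. In the test of a uniform compression set beforehand, scaling the 15 h changes by one common factor of 0.845 took the called probes from 15 to 4. Of these 4, 2 were among the 15. The bound of over 20 that would have counted against it was not reached. This decides little, because few probes were called before scaling, and leaving out a single array also took the 15 to between 0 and 4. Of 2 further fits, both chosen after that result, one with the treated arrays in blocks took them from 16 to 5, and one on the treated arrays alone with the control mean taken as fixed took them from 209 to 72. Of those 72, 41 changed more at 24 h than the factor predicts and 38 more than at 15 h, which argues against one factor below 1 as the whole of the difference in that fit, but it was chosen last of 3, so a uniform compression is left open. Whether such a factor would be technical, or a change in the cultures such as a partial return towards the control state, cannot be told apart here. Each time point has its own arrays, the ratios keep no signal levels, and the cell type markers were not tested.

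Same-numbered treated arrays deviate together: the real matching of numbers gave a mean correlation of 0.262, and 1 of 36 matchings, the real one, was that high, with 0.169 as the highest of the others. This is consistent with a source shared by arrays of one number, such as a culture or an array batch, which the labels do not name. For each control some number has to come out highest, because deviations cancel out within a treated group. By mean correlation, controls 2 and 4 went with number 1 (0.14 and 0.14) and controls 1 and 3 with number 2 (0.18 and 0.16). Controls 5 and 6 went with number 3 (0.2 and 0.31). That grouping was not tested, so whether such a source also reached the controls is left open. That numbers 1 to 3 mark the same source in the controls is argued against. The lowest mean correlation of one of these controls with its own number was -0.13, while control 1 went with number 2 at 0.18. No biological explanation was tested.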

How the results depend on the processing

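The settings without controls 1 and 5, with covariates from the within-group deviations, and with the treated arrays alone or in blocks of their own were chosen after the data had been seen. Counts are in the order 5 h, 15 h and 24 h against control, then 15 h against 5 h, 24 h against 15 h and 24 h against 5 h. The cause was not tested where none is given. Requiring a 1.5-fold change, a stricter condition, left 216, 1618, 1102, 1287, 9 and 964 probes. Quantile normalization gave 707, 1748, 1642, 1063, 0 and 1112. It widened the controls and narrowed the 15 h and 24 h arrays to one spread, which may by itself lower the counts. At 5 h, array weights gave 2399, controls 4 to 6 alone 897, the compared groups alone 1015, leaving out controls 1 and 5 2761, and 2 covariates 3199. For 24 h against 15 h, eBayes with trend and robust gave 2, array weights 45, leaving out controls 1 and 5 86, 2 covariates 210, and the compared groups alone 52. For 24 h against 5 h, 2 covariates gave 4331. The planned replicate block over all arrays gave 2098, 5103, 4139, 4322, 51 and 3621. A replicate block within the 9 treated arrays gave 5405, 209 and 4712 for the differences between times, and was not run against the control. It changes 2 choices: for 24 h against 15 h, the 9 treated arrays alone without pairs gave 88, and pairs with the controls kept in the variance gave 16. Controls 1 to 3 did not correlate best with their own number. Leaving out 1 array gave 644 (without 5 h replicate 1) to 2088 (without control 5) probes at 5 h, 3920 to 5274 at 15 h, 3033 to 4244 at 24 h, 2743 to 3109 for 15 h against 5 h, 0 to 4 for 24 h against 15 h, and 2099 to 2367 for 24 h against 5 h. Also at 5 h, 786 were left without replicate 3. With the controls split, correlations fell to 0.283 and 0.296 for 5 h and 15 h, 0.223 and 0.258 for 5 h and 24 h, and 0.807 and 0.827 for 15 h and 24 h, where each change also has fewer controls, so the cause was not tested. The 4 named probes kept their direction and their call in all 19 settings run for each comparison in which they had been picked as the extreme. Elsewhere calls did change: without controls 1 and 5, ILMN_2776687 was called at 5 h and ILMN_1231590 at 24 h. Quantile normalization took ILMN_2776687 from -3.11 and -2.98 to -1.59 at both times. That step sets the lowest value of every array equal. This probe was the lowest on control 1 and on every 15 h and 24 h array, so the equal -1.59 and part of the drop follow from the step. The balance of higher and lower probes turned in 3, 5, 5, 2, 7 and 1 of the settings run for the 6 comparisons (20 each against the control, 18 each between times), so it is not a stable result. For 24 h against 15 h, 4 higher and 11 lower became 28 and 17 with array weights and 133 and 76 with the block in treated arrays. Probes called in opposite directions at 15 h and 24 h, 0 in the main setting, numbered up to 4 in the others. The floor on low values, the filter on dim probes, the averaging of probes of a gene and the tests of gene lists were not run, because ratios keep no signal over background and the probes have no gene names here.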

Other observations

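The 102 probes raised in controls 1 and 5 were often called after glutamate, most of all at 5 h. Called without those arrays, a choice made after the data had been seen, 77 of them were higher and 4 lower at 5 h, 50 higher and 28 lower at 15 h, and 44 higher and 27 lower at 24 h. Higher at 5 h were 75.5% of them, against 5.29% of all probes. Their median ratio was 1.8 in control 1, 1.78 in control 5, 0.951 over the other controls, 1.43 at 5 h, 1.09 at 15 h and 1.02 at 24 h. At 52 of them the 15 h level was lower than the 5 h level by the test of that difference, and at 7 it was higher.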
